A study of Arabidopsis thaliana with 9 samples.

How the data were processed

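Whole wild-type (Col-0) Arabidopsis thaliana seedlings were profiled by RNA-seq. Per the labels, seedlings were moved 3 days after germination into 3 ml of liquid Murashige and Skoog medium and grown there for 7 days at 22 °C with 16 h of light and 8 h of dark. Fresh medium then carried 0.1% DMSO (the mock treatment), 10 µM abscisic acid (ABA, the plant hormone of drought and seed dormancy) or 10 µM of a compound the labels call iCB, and tissue was collected 3 h later. The labels give 3 groups of 3 libraries, and describe the replicates as independent biological ones.

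Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a strand-specific mRNA kit for DNBSEQ sequencing. Per the submitters' processing notes, FastQC, cutadapt, STAR, DESeq2 and the TAIR10 build were used; their versions, the counting program, its strand setting, its treatment of reads with several matches and the annotation release are not given in the sources used here. The deposited table holds raw counts, whole numbers of reads per gene locus for 37336 loci, with no normalization by the authors. It has 9 columns of counts. The names of 6 match the descriptions of the mock and ABA samples. The names of the other 3 match no label of any sample, so these 3 columns were not used in any step, and the iCB samples were not analysed here. The comparisons of iCB with mock and with ABA, which had been planned, were therefore not made. The comparison of ABA with mock, planned as part of a fit to all 9 libraries, was fitted to the 6 libraries of its own groups.

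Total counts ran from 21585450 to 22528897 in the mock libraries and from 22449479 to 22722904 in the ABA libraries. No pair of replicates agreed within sampling noise: a chi-square of their counts over its degrees of freedom ran from 6.64 to 14.7. Of the 37336 loci, 10178 had no count in the 6 libraries. Gene symbols, product names, exonic GC content, exonic length and overlaps came from a reference annotation of TAIR10.1, in which 37051 loci were found; because the count table rests on TAIR10, no coordinates are given and genes are identified by locus. GC content and length were found for 99.71% of the tested loci.

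Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by filterByExpr on the 2 groups (21092 loci), libraries were scaled by trimmed mean of M values (TMM), and ABA was compared with mock by the quasi-likelihood F test with robust dispersion estimates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are ABA minus mock, with a standard error (SE) of the fold change divided by the square root of F. Where a group holds few counts this SE is too small, for some genes below counting error alone. Levels are CPM (counts scaled to library size) after TMM scaling, as mean ± SD over 3 libraries. The median SE was 0.106 and the biological coefficient of variation 11.3%. Where the mock libraries held no count, a fold is a lower bound against a floor of 3 counts over the group, equal to 0.0416 CPM; floors cover counting error only.

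31 gene lists with 551 members were fixed by locus before the data were examined. 13 members whose locus carries no matching symbol in the reference were left out. 30 lists had at least 4 tested members and were tested with camera on limma-voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were run beside it. Genes were named by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, and 9 ABA genes whatever their values. It also takes up to 4 members with the smallest adjusted p from each list, plus called members that moved against the rest. Genes named outside this rule were picked after their values were seen.

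The steps were tested on simulated data made from these libraries' means and sizes. For ABA against mock, 40% of 50 genes changed by 0.5 on the log2 scale were recovered, 92% of 50 changed by 1, 95.9% of 49 changed by 2 and 98% of 50 changed by 4, among 20710 simulated genes. Few genes were changed, so the p needed for a call was stricter than in the real comparison and these shares do not carry over to it. 12 of the 174 calls (6.9%) were unchanged genes. All 5 shifted lists and 0 of 26 unshifted lists were called by camera. The simulated genes were drawn independently of each other. This result therefore does not show how camera behaves on real lists, whose members can vary together (estimated correlation up to 0.702).

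Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, relative log expression (RLE), upper-quartile or library-total scaling, no or a stricter filter (5 CPM), the replicate number as a block, an added minimum log2 fold change of 1, an adjusted p below 0.01, and each library left out in turn. Offsets for GC content and length and the restored list members were added after seeing the data.

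Reads of near-identical gene copies could have been split or dropped by the counting. This concerns COR15A and COR15B, LHCB1.4 and LHCB1.5, RBCS1B and RBCS2B, and several GSTU and PIP genes named here. The counting strand is not stated, so the counts of genes that overlap a neighbour on the opposite strand are uncertain. Among the genes named here these are LEA7, RAB18, ABI1, P5CS1, PYL7, SNRK2.5, GBF3, ABF3, COR15B, AAO3, GOLS4, JAZ12, ARR8, ARR9, CKX5, GASA6, LHCB1.5, LHCA5, CDKB1;1, KNOLLE, EXPA7, LNK1, BOA, KCS2, FAR1, UPM1, G6PD3, CASP5, XCP1, CESA4 and CESA8. AT1G15125, CKX5, CYCD3;1, GSTU17 and CESA4 overlap a neighbour on their own strand.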

Results

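Gene expression was measured in whole seedlings kept for 3 h with 0.1% DMSO (mock, 3 libraries) or with 10 µM ABA (3 libraries). A DMSO content is given for mock only, so whether the ABA medium held the same amount is not known here. The mock libraries held 21585450 to 22528897 counts and the ABA libraries 22449479 to 22722904, so depth differed little between the groups. Pearson's r of log2 CPM across genes was 0.983 to 0.988 between mock libraries, 0.992 between ABA libraries and 0.873 to 0.888 between groups. The first principal component carried 88.6% of the variance and parted the groups. The second carried 4.4% and set mock replicate 1 (30.7) against mock replicate 3 (-30.3). The series title speaks of ABA-responsive expression under iCB; the iCB samples were not analysed here, and the comparison below is the reference response, that of ABA against mock.

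ABA raised the genes most used as markers of its action and lowered most of the receptors that bind it. RD29A (AT5G52310), a desiccation-responsive gene, went from 138 ± 62.4 CPM in mock to 6247 ± 54.7 CPM in ABA (SD, n = 3), a log2 fold change of 5.50 ± 0.37 (SE) or 45.3-fold. The dehydrin gene RAB18 (AT5G66400) rose by 9.06 ± 0.28, from 2.25 ± 0.93 to 1202 ± 104.0 CPM. HAI1 (AT5G59220), a protein phosphatase 2C that dampens ABA signalling, rose 343-fold, and P5CS1 (AT2G39800), of proline synthesis, rose 46.2-fold. The receptor gene PYL4 (AT2G38310) fell 38.2-fold, from 187 ± 18.9 to 4.89 ± 0.52 CPM. In edgeR's quasi-likelihood test the adjusted p of these 5 genes was at most 5.01e-05, and their ABA libraries did not overlap their mock libraries.

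**Figure D1:**
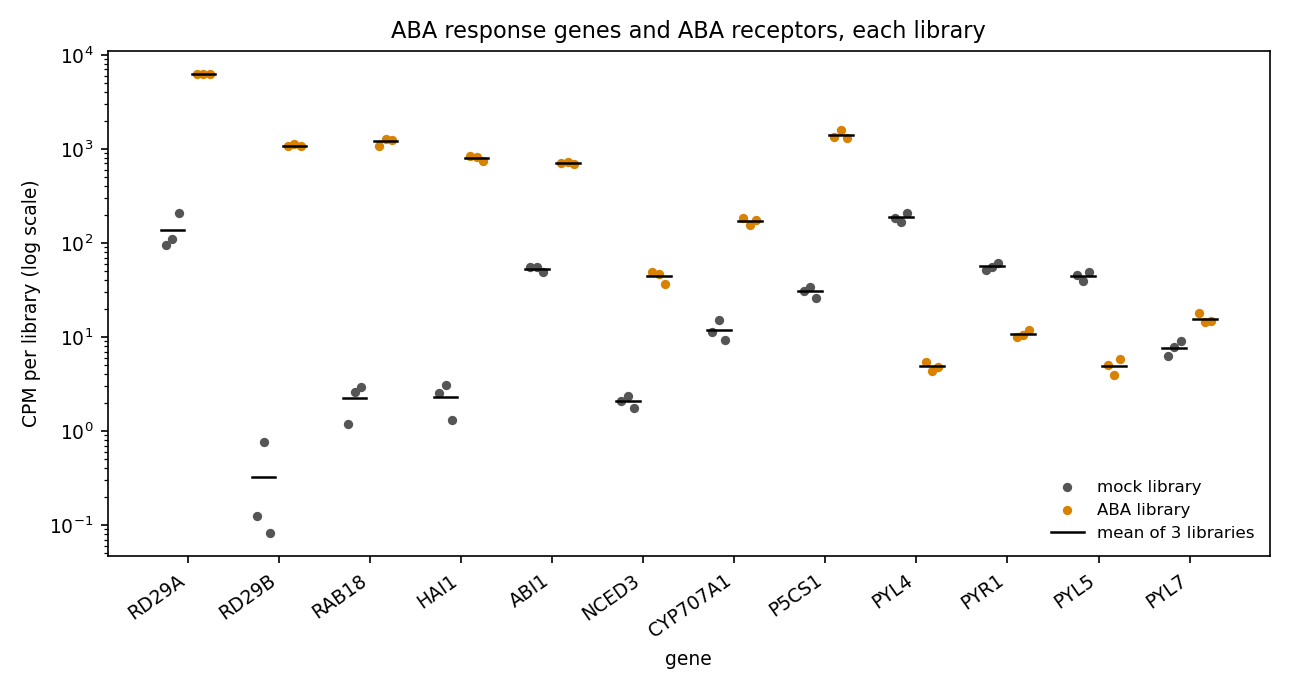
CPM of 12 genes on a log axis, 1 point per library, with mock in grey, ABA in orange and a bar at the mean of 3 libraries. The ABA and mock libraries did not overlap for any of these genes; PYL4, PYR1 and PYL5 were lower in ABA and the other 9 genes higher.

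Of 21092 genes tested, 6537 (30.99%) were higher in ABA and 6205 (29.42%) lower. With a log2 fold change of at least 1 as well, 2471 were higher and 1847 lower, and with at least 2 there were 991 higher and 484 lower. The groups did not overlap for 14312 genes (67.9%), against 10% by chance with 3 against 3. Of the 8350 genes not called, 5191 had a 95% interval of the log2 fold change, taken from the normal distribution, within ±0.5. With so few libraries such an interval is too narrow, so this number is too high. The balance of the directions rested on the scaling: 51.3% of the calls were higher with TMM, 33.7% with upper-quartile factors and 32.1% with library totals. Library totals moved all log2 fold changes by -0.23 (median) and upper-quartile factors by -0.21, so small changes below are relative to the TMM centre.

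The 8 largest rises included 4 genes of the late embryogenesis abundant (LEA) family, known from drying seeds. AT3G17520 rose by 11.93 ± 0.17 to 564 ± 43.6 CPM, LEA7 (AT1G52690) by 11.27 ± 0.11 to 937 ± 14.6 CPM and AT3G02480 by 11.16 ± 0.15 to 1762 ± 63.2 CPM. The tryptophan-rich sensory protein gene TSPO (AT2G47770) rose by 11.92 ± 0.22 to 344 ± 4.66 CPM, and RD29B (AT5G52300) by 11.71 ± 0.38 to 1087 ± 28.2 CPM. Without mock replicate 2, which held most of their mock counts, these last values were 12.84 and 13.29. Over the 3 mock libraries AT3G17520, LEA7, AT3G02480 and TSPO held only 10, 27, 55 and 6 counts, so their SEs are too small. The other 3 had no count in any mock library. GASA3 (AT4G09600) was at least 359-fold higher, a further LEA gene, AT2G42560, at least 311-fold, and AT1G04560 of the AWPM-19-like family at least 286-fold.

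The largest fall was that of CRK30 (AT4G11460), a cysteine-rich receptor-like kinase, which fell by 7.65 ± 0.41 from 42.8 ± 7.72 CPM; without ABA replicate 1 it fell by 8.74, and in limma-voom it fell by 8.30. PYL6 (AT2G40330) fell by 7.27 ± 0.30 and the MATE efflux gene AT4G21903 fell by 6.15 ± 0.39. PYL6 held only 9 counts over the 3 ABA libraries, so its SE is too small. PP2-A5 (AT1G65390), a phloem lectin-like gene, fell by 5.58 ± 0.30 and AT1G27020 fell by 5.20 ± 0.50. The acyltransferase gene AACT1 (AT5G61160) had a log2 fold change of -5.51 ± 0.79, or -4.84 without mock replicate 3, and the methyltransferase gene AT1G15125 one of -5.48 ± 0.59, or -6.17 without ABA replicate 1. The adjusted p of these 8 falls, PYL4 included, was at most 2.37e-03 in edgeR's quasi-likelihood test.

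**Figure D2:**
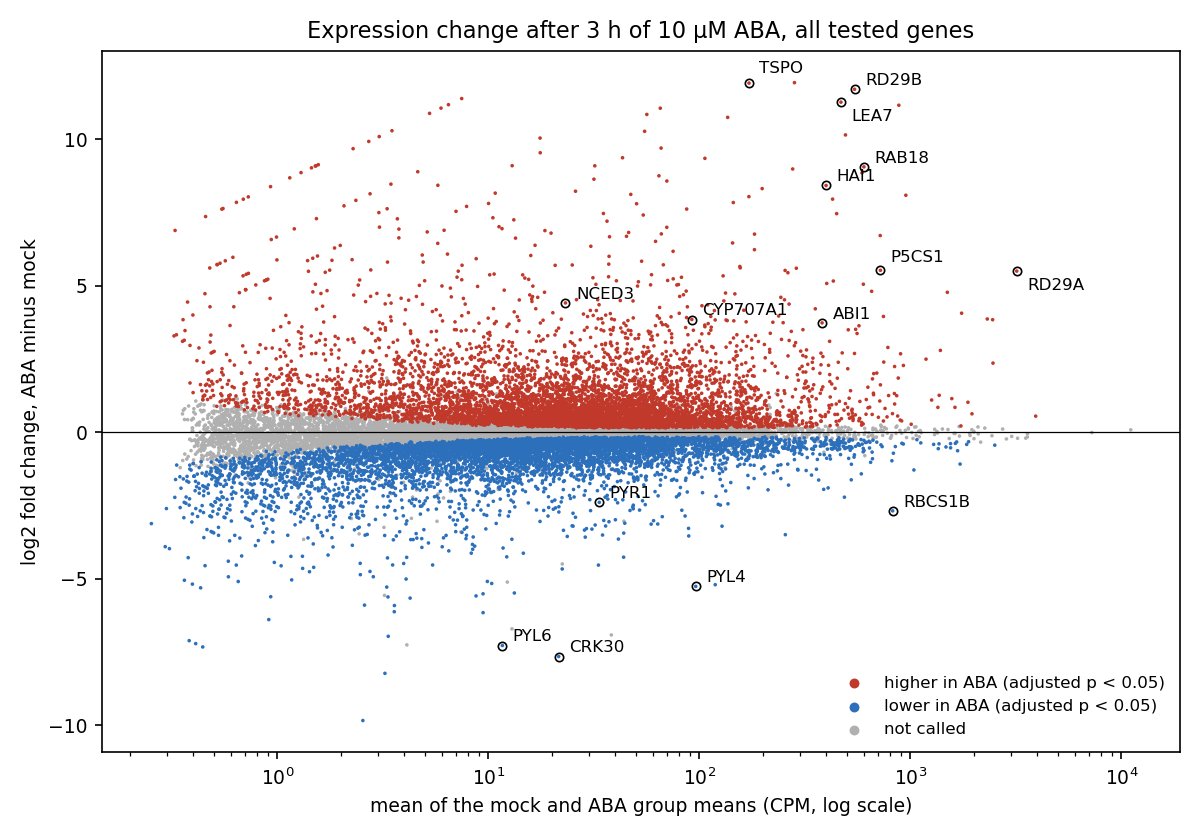
Log2 fold change of ABA minus mock against the mean of the group means in CPM (log axis), 1 point per gene, with called genes in red (6537 higher) and blue (6205 lower) and named genes circled. Lines of points at the upper left are genes with few or no mock counts, whose fitted values depend on the prior count; RD29A stands far to the right at 5.50 and PYL6 and CRK30 at the bottom.

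Most receptor genes fell, while genes of the phosphatases that act after them and many SnRK2 kinase genes rose. Among 9 tested receptor genes of the PYR/PYL family, 7 fell and 1 rose, with a median log2 fold change of -1.52 (camera adjusted p = 3.31e-03, adjusted p = 0.221 with an estimated correlation). PYR1 (AT4G17870) fell by 2.39 ± 0.10 and PYL5 (AT5G05440) fell by 3.19 ± 0.15, while PYL7 (AT4G01026) rose by 1.03 ± 0.15 and PYL9 stood at 0.19 ± 0.13. All 9 clade A protein phosphatases 2C, which the receptors inhibit, rose (median 4.61, camera adjusted p = 6.92e-07, adjusted p = 0.163 with an estimated correlation). ABI1 (AT4G26080) rose by 3.74 ± 0.08, HAB1 by 4.61 ± 0.10, HAB2 by 2.27 ± 0.06 and HAI2 by 9.35 ± 0.19. Of 10 genes of the SnRK2 kinase family, some of whose members those phosphatases hold in check, 7 rose and 1 fell (median 0.47, camera adjusted p = 9.47e-03, adjusted p = 0.163 with an estimated correlation). With library totals 5 rose and 1 fell (median 0.24). SNRK2.7 rose from 2.83 ± 0.46 to 99.9 ± 2.63 CPM and SNRK2.6, the guard-cell kinase OST1, by 2.17 ± 0.09, while SNRK2.5 fell by 0.67 ± 0.17.

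Transcription regulators tied to ABA rose in 24 of 28 cases and fell in 1 (median 3.49, camera adjusted p = 3.57e-11, adjusted p = 0.162 with an estimated correlation). The bZIP factor genes ABF2, ABF3 and GBF3 rose by 2.69 ± 0.06, 3.74 ± 0.11 and 3.98 ± 0.08, and NAC019 by 5.29 ± 0.15. WRKY18 fell by 1.17 ± 0.22. All 25 tested dehydrin, LEA and dehydration marker genes rose, with a median of 6.45 that stayed at 6.45 with EM1, which had no mock count, set to its bound (camera adjusted p = 6.49e-15, adjusted p = 0.117 with an estimated correlation). COR15A (AT2G42540) reached 1896 ± 26.8 CPM from 6.96 ± 1.73, COR15B rose by 6.23 ± 0.10, and the caleosin gene RD20 rose by 8.85 ± 0.14. The spread of this list between mock libraries, a median SD of 0.388 on the log2 scale, was larger than between ABA libraries (0.079), against 0.119 and 0.110 over all genes. Some members held few counts over the mock libraries (27 for LEA7, 23 for RD29B), where counting error widens the spread. How much of the difference lies between plants was not tested.

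Genes that make ABA and genes that remove it rose together. Of 8 biosynthesis genes, 7 rose (median 1.68, camera adjusted p = 2.19e-03, adjusted p = 0.163 with an estimated correlation). NCED3 (AT3G14440), which cleaves the carotenoid precursor, went from 2.07 ± 0.31 to 44.3 ± 6.83 CPM, ABA1 rose by 2.25 ± 0.07, AAO3 by 1.76 ± 0.09 and ABA4 by 1.21 ± 0.07, while ABA2 stood at -0.10 ± 0.12. Among 13 genes of catabolism, conjugation and transport 9 rose and 2 fell (median 0.86, camera adjusted p = 9.47e-03, adjusted p = 0.163 with an estimated correlation). The 8'-hydroxylase genes CYP707A1 (AT4G19230), CYP707A2 and CYP707A4 rose by 3.85 ± 0.18, 3.03 ± 0.11 and 3.02 ± 0.22, and the exporter gene ABCG25 by 1.82 ± 0.09. The transporter genes ABCG31 and NPF4.6 fell, with values of -1.14 ± 0.29 and -0.34 ± 0.10; without ABA replicate 2, NPF4.6 no longer passed (edgeR adjusted p = 0.0539).

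Osmoprotectant and carbohydrate genes rose in 10 of 11 cases (median 2.45, camera adjusted p = 5.34e-06, adjusted p = 0.162 with an estimated correlation). The sucrose synthase gene SUS3 rose by 6.18 ± 0.08, the beta-amylase gene BAM1 by 3.76 ± 0.07 and the galactinol synthase gene GOLS4 by 5.17 ± 0.12. Of 19 aquaporin genes 12 rose and 2 fell (median 0.69, camera adjusted p = 3.31e-03, adjusted p = 0.408 with an estimated correlation). PIP1;4 rose by 1.85 ± 0.07, PIP2;6 by 1.33 ± 0.09 and TIP2;2 by 1.55 ± 0.12, while TIP4;1 fell by 0.59 ± 0.14. PIP2;4, at -0.63 ± 0.21, lost its call with no filter and when any library but mock replicate 3 was left out.

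Surface lipid and senescence genes also rose. Of 12 cuticular wax genes 11 rose (median 1.6, camera adjusted p = 4.74e-05, adjusted p = 0.314 with an estimated correlation). The alkane-forming CER1 rose 48.5-fold to 564 ± 39.4 CPM, CER3 rose by 2.1 ± 0.11 and the wax ester synthase gene WSD1 by 4.57 ± 0.26. CER4, at -0.42 ± 0.16, passed in edgeR but not in DESeq2 or limma-voom, nor when any library but mock replicate 3 was left out. All 10 suberin genes rose (median 2.61, camera adjusted p = 5.34e-06, adjusted p = 0.299 with an estimated correlation), among them KCS2 by 4.17 ± 0.12, the regulator MYB41 by 4.99 ± 0.16 and FAR1 by 2.28 ± 0.11. All 11 senescence and chlorophyll breakdown genes rose (median 2.86, camera adjusted p = 1.99e-06, adjusted p = 0.163 with an estimated correlation). The transcription factor gene NAP rose by 5.71 ± 0.12, the stay-green gene NYE1 by 2.94 ± 0.07 and the sugar transporter gene SAG29 from 1.09 ± 0.23 to 552 ± 87.8 CPM.

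**Figure D3:**
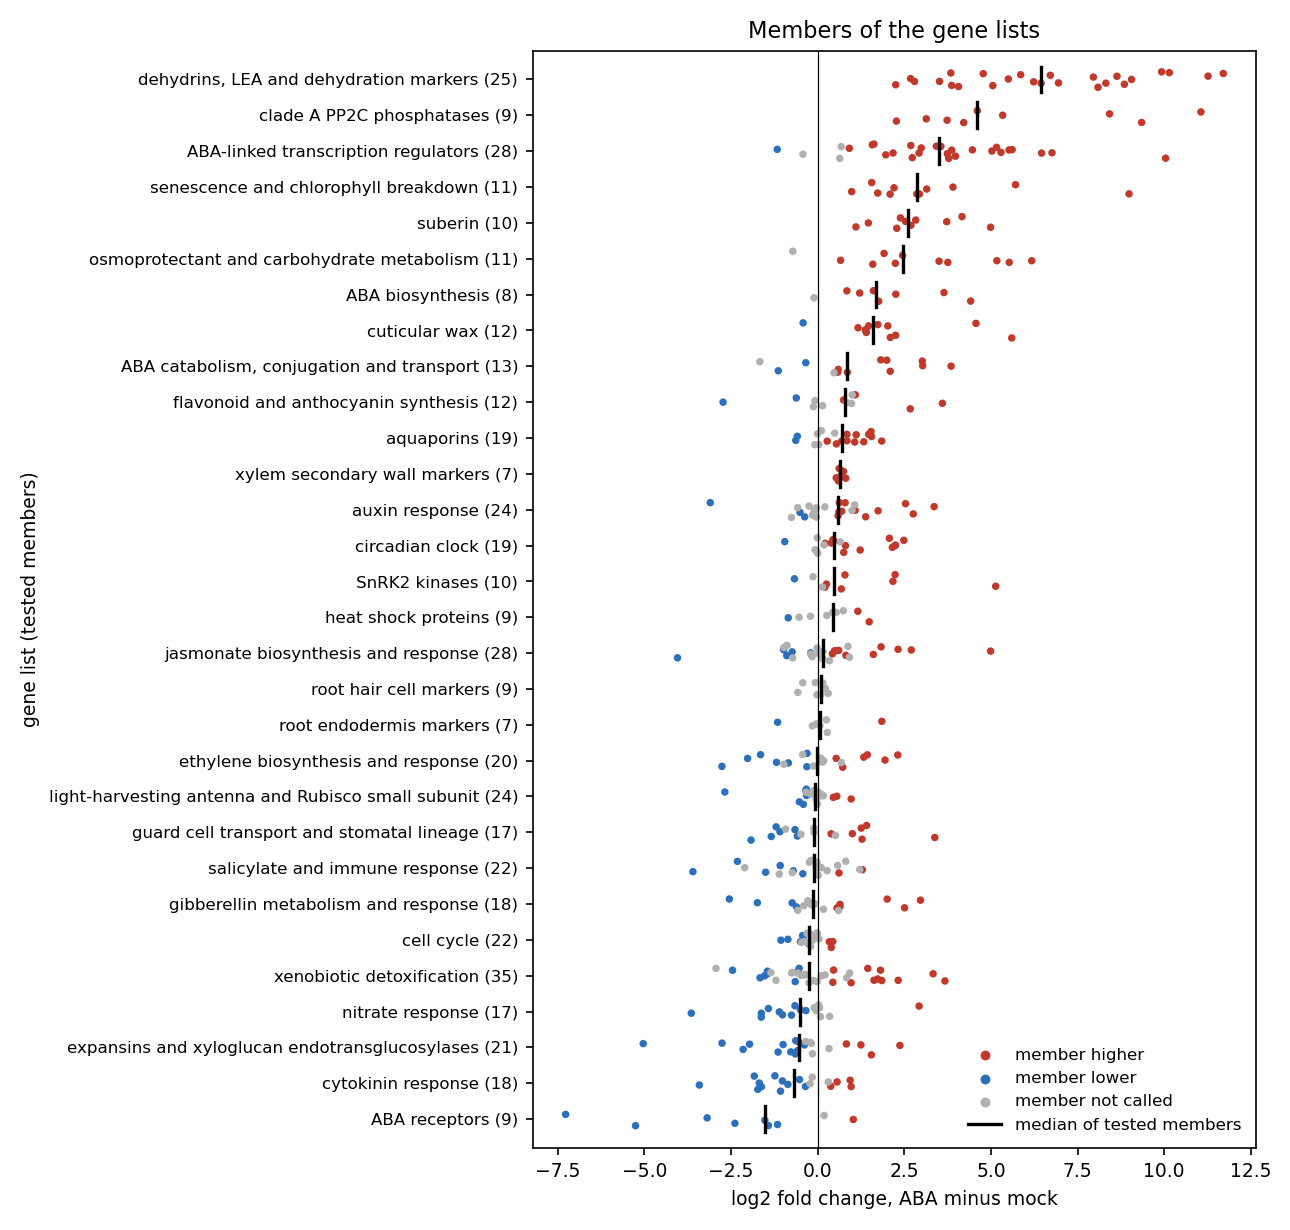
Log2 fold change of ABA minus mock for each tested member of 30 gene lists, with called members in red and blue, uncalled ones in grey, and a bar at the list median. Medians ran from -1.52 for the ABA receptors to 6.45 for dehydrins, LEA and dehydration markers; the vertical scatter within a list has no meaning.

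Lists of other hormones changed in part. Cytokinin response genes fell in 11 of 18 cases and rose in 4 (median -0.69, camera adjusted p = 0.0318, adjusted p = 0.516 with an estimated correlation); the list was not called with library totals or without ABA replicate 2. The response regulator genes ARR7 and ARR8 fell, at -1.73 ± 0.10 and -0.86 ± 0.09, and the cytokinin oxidase gene CKX4 fell by 3.41 ± 0.21. ARR9 and ARR16 rose by 0.56 ± 0.08 and 0.94 ± 0.24. CKX5 rose by 0.97 ± 0.27, a call lost without ABA replicate 1, and CKX7 by 0.38 ± 0.12, a call lost with library totals, upper-quartile factors, the stricter filter and without several single libraries.

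The other 5 hormone lists were not called by camera with TMM scaling, although single members moved far; with library totals the auxin list was called higher (adjusted p = 0.0404). Of 28 jasmonate genes 10 rose and 5 fell; CYP94B3, which oxidises the active jasmonate, rose 31.8-fold and the ethylene and jasmonate factor gene ORA59 fell by 4.05 ± 0.19. JAZ11 and JAZ12 rose by 1.83 ± 0.08 and 1.61 ± 0.08, and JAZ6 fell by 0.98 ± 0.08. Of 24 auxin genes 11 rose, with GH3.6 and GH3.5, which conjugate auxin, up by 3.36 ± 0.08 and 2.76 ± 0.17, and 3 fell, among them PIN7 at -0.51 ± 0.09. Of 20 ethylene genes 6 rose and 7 fell; ERS2 rose by 1.94 ± 0.15 and ERF2 fell by 2.02 ± 0.19. Of 18 gibberellin genes 6 rose and 5 fell; GA2OX6, which inactivates gibberellin, rose by 2.96 ± 0.10, the DELLA gene RGL3 by 2.01 ± 0.12, and GASA6 fell by 2.55 ± 0.24. Of 22 salicylate and immune genes 2 rose and 6 fell, with WRKY70 at 1.29 ± 0.18 and PAD4 at -1.08 ± 0.16. Camera's adjusted p for these lists was 0.321, 0.140, 0.952, 0.952 and 0.525. With library totals 10 gibberellin genes fell and 6 rose, 8 jasmonate genes fell and 10 rose, 5 auxin genes fell and 9 rose, and 9 immune genes fell and 2 rose.

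Genes of cell expansion and nitrate response fell. Expansin and xyloglucan endotransglucosylase genes fell in 12 of 21 cases and rose in 4 (median -0.54, camera adjusted p = 0.0226, adjusted p = 0.171 with an estimated correlation); with library totals the list was not called. EXPA15, EXPA5 and EXPA1 stood at -2.76 ± 0.12, -1.97 ± 0.10 and -2.15 ± 0.12, whereas XTH24, XTH22, XTH30 and EXPA11 rose by 1.55 ± 0.07, 2.37 ± 0.23, 1.25 ± 0.13 and 0.83 ± 0.14. Of 17 nitrate response genes 10 fell and 1 rose (median -0.50, camera adjusted p = 0.0146, adjusted p = 0.314 with an estimated correlation). The regulator gene LBD38 fell by 1.63 ± 0.08, UPM1 fell by 1.11 ± 0.06 and the plastid glucose-6-phosphate dehydrogenase gene G6PD3 fell by 1.63 ± 0.10, and BT1 rose by 2.93 ± 0.10. Cell cycle genes fell in 7 of 22 cases and rose in 3 (camera adjusted p = 0.0930); the list was called lower without ABA replicate 3 (adjusted p = 0.0423). Among its members the D-type cyclins CYCD3;3 and CYCD3;1 fell, at -1.06 ± 0.10 and -0.86 ± 0.11, and the inhibitor gene KRP1 rose by 0.44 ± 0.08. The 3 rises, of KRP1, CDKB1;1 and KNOLLE, were not called with library totals, under which 16 members fell; KNOLLE and CDKB1;1 were not called with upper-quartile factors either, nor KNOLLE with the stricter filter or without any single library but ABA replicate 1.

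Of 24 light-harvesting antenna and Rubisco small subunit genes 3 rose and 6 fell, or 2 and 12 with library totals (camera adjusted p = 0.368). RBCS1B (AT5G38430) fell from 1425 ± 83.9 to 223 ± 24.9 CPM and RBCS2B fell by 0.53 ± 0.12. LHCB1.5, LHCA5 and LHCB1.4 rose by 0.55 ± 0.12, 0.45 ± 0.11 and 0.97 ± 0.26; LHCA5 was not called with library totals or upper-quartile factors, nor LHCB1.4 without mock replicate 1, ABA replicate 1 or ABA replicate 2. Circadian clock genes rose in 12 of 19 cases and fell in 1 (median 0.47, camera adjusted p = 4.62e-03, adjusted p = 0.299 with an estimated correlation); with library totals 8 rose and 4 fell. LNK1, RVE2, CCA1 and BOA rose by 2.07 ± 0.07, 2.24 ± 0.09, 2.16 ± 0.11 and 2.24 ± 0.13, and CHE fell by 0.95 ± 0.09.

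Detoxification, flavonoid and heat shock lists were not called (camera adjusted p = 0.952, 0.450 and 0.578). Of 35 xenobiotic detoxification genes 11 rose and 8 fell, or 8 and 11 with library totals (median -0.25). Those with the smallest adjusted p were rises: the glutathione transferase genes GSTU17 and GSTU5 rose by 2.32 ± 0.08 and 1.81 ± 0.07 and the NAC factor gene NAC032 by 3.67 ± 0.14. Of 12 flavonoid genes 4 rose and 2 fell (3 and 4 with library totals); PAP2 rose by 3.6 ± 0.31, and the regulator genes MYB111 and MYB12 fell, at -2.73 ± 0.19 and -0.62 ± 0.17. Of 9 heat shock genes HSP70 rose by 1.49 ± 0.27; HSP17.6A (1.16 ± 0.40) and HSP17.6II (-0.85 ± 0.29) passed narrowly and lost their calls with no filter and without several single libraries, HSP17.6A also with library totals and upper-quartile factors and HSP17.6II with GC and length offsets.

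Guard cell and stomatal lineage genes rose in 6 and fell in 6 of 17 cases, or 5 and 9 with library totals (camera adjusted p = 0.952). The potassium channel genes GORK and KAT1 rose by 3.38 ± 0.10 and 1.41 ± 0.11 and the anion channel gene SLAH3 by 1.26 ± 0.07. The proton pump gene AHA2 fell by 1.09 ± 0.11. AHA1 rose by 0.39 ± 0.07, a call lost with library totals. None of 9 root hair markers was called by edgeR, DESeq2 or limma-voom, and 2 were lower at an unadjusted p below 0.05; RSL4 and ADF8 stood at -0.57 ± 0.22 and -0.43 ± 0.18, and both were called lower without mock replicate 3, with library totals, with upper-quartile factors and with GC and length offsets, RSL4 also with RLE factors and with no filter, and ADF8 with the stricter filter. EXPA7, at 0.30 ± 0.16, was called higher without mock replicate 2 (edgeR adjusted p = 0.0466). Of 7 endodermis markers CASP4 fell by 1.16 ± 0.21 and CASP5 rose by 1.85 ± 0.41, or by 2.535 without mock replicate 1. All 7 xylem secondary wall markers rose (median 0.64, camera adjusted p = 6.37e-03, adjusted p = 0.408 with an estimated correlation), for instance XCP1 by 0.62 ± 0.07, XCP2 by 0.54 ± 0.07, CESA4 by 0.68 ± 0.08 and CESA8 by 0.81 ± 0.11; 6 of the 7 were called with library totals. Only OLEO4 of the seed maturation genes passed the filter (-0.19 ± 0.29), so that list was not tested in the main fit. With no filter 13 of its genes were tested and the list was not called (camera adjusted p = 0.941).

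In all, camera with the preset correlation called 13 lists higher and 4 lower of 30. With an estimated correlation no list passed after adjustment (lowest adjusted p = 0.117), 8 were higher at an unadjusted p below 0.05, and fry called 18 higher and 4 lower, adding the guard cell, jasmonate, auxin, gibberellin and detoxification lists. Adjusted over the list alone, 26 of the 31 lists had the same counts of higher and lower members. The counts differed for the clock (14 higher, 1 lower), expansins (4 and 13), immune genes (2 and 5), detoxification (11 and 7) and heat shock (1 and 0). Median and mean differed in sign for the guard cell, gibberellin, detoxification and root hair lists, and for the guard cell, ethylene and root hair lists fry's direction was opposite to camera's.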

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

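The offsets for GC content and length and the restored list members were chosen after seeing the data. The 6537 higher and 6205 lower genes became 6109 and 5618 in DESeq2, 6612 and 6137 in limma-voom, 6482 and 6259 with RLE factors, 6442 and 6379 with no filter, and 5119 and 5341 with the stricter filter, which tested 15864 genes. At an adjusted p below 0.01 they were 5320 and 4615. With each library left out in turn they ran from 5883 to 6258 and from 5454 to 6139. Offsets for GC content and length gave 6653 and 6029. The minimum log2 fold change of 1 left 2471 and 1847, by its own construction. Library totals gave 4475 and 9459 and upper-quartile factors 4618 and 9100; both moved the centre of all fold changes, by -0.229 and -0.208. Of the 17 lists called, 17 were called on ranks, with no filter and with the restored members. Fry called 22, library totals 16 (cytokinin response and expansins lost, auxin response gained) and single libraries left out 16 to 18 (cytokinin response lost without ABA replicate 2, cell cycle gained without ABA replicate 3). With an estimated correlation 0 lists passed; the cause was not tested.

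The replicate numbers were also fitted as a block, which gave 6586 higher and 6229 lower genes, with 96.9% of the calls shared, and 16 lists, without cytokinin response. Among the genes named in the report it called RSL4 and ADF8 lower and no longer called PIP2;4, CER4 and HSP17.6II. Nothing in the labels pairs the samples. Deviations of libraries with the same number correlated at 0.066, 0.084 and 0.203, and each library correlated best with its own number, a hint from the data and not the design.

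For 179 named genes, 2558 of 2667 values under an alternative kept direction and side of the threshold, 89 were no longer past it, 17 newly passed it and 3 changed sign; 151 genes kept both throughout. The sign changes were those of 2 genes never called. PRP3, a root hair marker at 0.221, was at -0.009 with library totals and ran from -0.022 to 0.459 with single libraries left out. OLEO4, at -0.189, ran from -0.386 to 0.062 with single libraries left out and was at -0.416 with library totals. The cause was not tested.

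The alternatives planned for iCB against mock, iCB against ABA, the 3 groups together, the overlap of the 2 compounds, the slope and the ratio were not run, because the iCB samples were not analysed here. The planned fit of all 9 libraries was not run either, so the fit to only the 6 libraries of the 2 groups, planned beside it, is the one reported. Every alternative used those 6, or all but 1 of them where a library was left out. At this depth the median SE was 0.106, and 5191 of the 8350 genes not called had a 95% interval from the normal distribution within ±0.5. That interval is too narrow for so few libraries, so 5191 is too high. For the other genes not called a change of that size was not excluded.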

Other observations

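The phrase groups, the snoRNA pattern, the offsets for GC content and length, the snoRNA test on trends estimated without those genes, and the clock test and its other scalings below were chosen after the results they bear on were seen. Genes were also grouped by phrases in their product names (780 phrases with at least 15 tested genes), an exploratory screen in which groups overlap. Camera with the preset correlation called 46 phrases higher and 81 lower; none passed with an estimated correlation after adjustment (adjusted p = 0.513 for every group below except the 2 named), and 66 had an unadjusted p below 0.05. Of 363 genes named ribosomal, 279 fell and 18 rose, with a median log2 fold change of -0.45 (camera adjusted p = 1.69e-17). Of 240 pentatricopeptide genes, whose products mostly act on organelle RNA, 105 fell and 8 rose (median -0.30, adjusted p = 4.05e-05), or 168 and 2 with library totals (median -0.53). RNA helicase genes fell in 40 of 57 cases (median -0.38, adjusted p = 5.71e-05, adjusted p = 0.515 with an estimated correlation) and chaperonin genes in 14 of 17 (median -0.43, adjusted p = 7.68e-04, adjusted p = 0.515 with an estimated correlation). Of 75 genes with the phrase receptor-like protein in their product names, 43 fell and 10 rose (median -0.60, camera adjusted p = 5.93e-04). This phrase also takes in receptor-like protein kinases such as CRK30. Of 90 C1 domain genes 46 fell and 14 rose (median -0.62, camera adjusted p = 0.0206).

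Other groups rose. Of 16 genes of 3-ketoacyl-CoA synthases, which lengthen fatty acids and of which 4 stand in the wax or suberin lists, 13 rose and none fell (median 1.55, camera adjusted p = 1.95e-04). Genes of CBL-interacting kinases rose in 15 of 20 cases (median 0.79, adjusted p = 2.28e-03), and NAC domain genes rose in 30 and fell in 10 of 56 cases (median 0.55, adjusted p = 8.72e-03). Of 217 RING/U-box genes 117 rose and 30 fell (median 0.31, adjusted p = 2.55e-04); with library totals 81 rose and 49 fell (median 0.08). The medians of the groups named here kept their sign under all 4 scalings, which was not so for every group called. With library totals the ribosomal median was -0.67 and the 3-ketoacyl-CoA synthase median 1.32.

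The number of genes called was set against 3 technical explanations. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called 12742 genes; the highest other split called 0, and 67 to 186 genes had an unadjusted p below 0.05 in them. For lists the real split called 17 and the highest other 20, so 4 of the 10 splits called as many, and 10 splits are too few for a share under 0.05. Every other split mixes mock and ABA libraries in both of its groups. The ABA effect then widens the spread within groups, which keeps gene calls low, and part of it remains between the groups. Neither the gene counts nor the list counts of those splits measure chance, so the splits decide nothing here. Without the 200 most abundant genes, which held 23.0% of mock and 24.1% of ABA counts, library totals called 13547 genes, 33.6% of them higher. Those shares are close and 200 genes are few beside 12742 calls, so the number called could hardly have fallen. The number therefore cannot decide this explanation. The share of higher calls under library totals was 32.1% with all genes, so that balance did not rest on these 200. Removing the GC and length trends left 12682 calls, and 96% of the main calls were called again in the same direction. That argues against such a bias as the source of most calls. It does not settle the question for single groups of genes, such as the snoRNA genes below.

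Counts for genes of small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, were lower. Of 43 such genes 32 fell and none rose (median -1.12, median SE 0.32), with 25 lower in DESeq2 and 31 in limma-voom. Most had few counts: only 3 passed the stricter filter (5 CPM), and 2 of those fell. The libraries were made with an mRNA kit, so how far these counts follow the level of mature snoRNA was not tested. That 22 of the 29 snoRNA genes without an overlapping gene fell argues against such genes as the source. Another 118 genes no longer than the longest snoRNA gene stood above the snoRNA median by 0.92 (95% bootstrap interval 0.72 to 1.19). The bootstrap resampled genes as if independent, so its interval leaves out the spread between libraries. The gap argues against an equal loss of all RNA up to 290 nt. It cannot decide on a loss that grows as the RNA gets shorter, because most of the 118 were longer than most snoRNA genes. Only 13 of the 118 were at most 150 nt, as 90% of the snoRNA genes were. These 13 had a median of -0.53 (7 lower, 4 higher), and no interval was computed for them. A GC or length bias cannot be told apart from a change in these genes: offsets from trends over all genes left 10 lower and 3 higher (median -0.27, median SE 0.33), calls that ended because the fold shrank, whereas trends estimated without the snoRNA genes, tried after that, left 25 lower and 1 higher (median -0.93, median SE 0.33). The first trend is partly set by the snoRNA genes themselves, and the second is extended to their lengths from few others. As a biological counterpart, nucleolar and rRNA-processing protein genes moved the same way, with a median of -0.66 (51 of 69 lower, 9 higher, camera p = 5.83e-09, p = 0.0526 with an estimated correlation).

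Clock genes rose as a list with the preset correlation (adjusted p = 0.299 with an estimated correlation; 8 higher and 4 lower with library totals), which a shift in the time of collection could also give. At many times of day such a shift would move morning and evening genes in opposite directions, but at some it could move both the same way. The evening set rose (4 of 6 higher, none lower, median 0.61, fry adjusted p = 1.18e-03), as did the morning set (6 of 9 higher, none lower, median 1.23, fry adjusted p = 4.01e-04). With library totals both sets still rose (evening 3 higher and 1 lower, median 0.38, fry adjusted p = 7.60e-03; morning 5 higher and 1 lower, median 1.00, fry adjusted p = 6.86e-04). Not every member moved: LHY, LNK2 and LUX were not called. CHE, the 1 gene of the clock list called lower, is in neither set. Fry does not compare a set with the other genes and called 18 of the 30 lists higher, so its p adds little. For the genes in these 2 sets, the joint rise argues against a shift that moves them in opposite directions as the whole cause. It cannot exclude a shift that moves both the same way.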
